A study of Mus musculus and Homo sapiens with 16 samples.

How the data were processed

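RNA was measured in 10 libraries of mouse skin epithelium from C57BL/6 animals labelled Klf5+/- (heterozygous) or Klf5-/- (knockout). The E17.5 set held 3 libraries of each genotype. Per the labels' protocols, embryonic epidermis was peeled after dispase, dissociated with trypsin and sorted for cells negative for DAPI and CD45 and positive for integrin alpha 6, and poly(A) mRNA libraries were made by a service provider. The other set, whose titles carry the letters HFD, an abbreviation the labels do not expand, held 2 libraries of each genotype. Per the labels' protocols, it was peeled epidermis ground in liquid nitrogen without sorting, and its libraries were made with a directional kit; no developmental stage is given for it. Chromatin was measured in 1 sample per assay: H3K27ac ChIP-seq (an acetylated histone mark of active promoters and enhancers), KLF5 ChIP-seq and ATAC-seq (open chromatin) from sorted E17.5 epithelium, and H3K27ac and KLF5 ChIP-seq from HaCaT, an immortal human keratinocyte line. The ATAC library has Het in its title and wild type as its genotype. An IgG ChIP sample was not analysed here.

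The authors deposited raw read counts per Ensembl gene, 1 file for each RNA library. Per the submitters' processing notes, reads were processed with STAR 2.6.0b and HTSeq on mm10 (GRCm38); the notes do not give the strand setting of the counting. The HFD files also hold RPKM values, which the authors deposited beside the counts. These equalled the counts divided by exon length and by the file's total within a relative deviation of 7.6e-14, and were not used in any test. Peaks were called with MACS2, per the submitters' processing notes, which also name Bowtie 1.0.1 and Bowtie2 2.2.3. The control library and the calling threshold are not given in the sources used here. Each deposited peak list belongs to 1 sample, and the peak names contain the word MERGE without saying what was merged. The deposited lists give for each peak a fold enrichment at its summit, a ratio over the local background, with −log10 p and −log10 q values; these are the authors' values and were used only to describe, rank or filter peaks within a list. A deposited integer score repeats the q value and was not used. Mouse peaks are on mm10 and HaCaT peaks on hg19 (GRCh37), and no coordinate was converted between builds.

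Gene symbols and coordinates came from the HFD count files, which pair all 39179 gene identifiers with symbols; 37607 of the identifiers were also in a separate table of gene names. Reads that named no gene stayed out of library sizes and tests. They made up 13.54 to 16.85% of the reads at E17.5 and 13.38 to 16.46% in the HFD set, among them 4.70 to 6.15% and 7.95 to 9.09% that aligned to more than 1 place. Genes with near-identical copies, such as the Sprr2, Lce, Stfa, Hspa1, haemoglobin and C4 genes, lose such reads, so their levels are less certain, and reads of antisense partners cannot be told apart where the counting did not use strand. Total counts on genes ranged from 34965243 to 46445546 in the E17.5 Klf5+/- libraries and from 34486898 to 38597737 in those labelled Klf5-/-. They ranged from 34286575 to 36984884 in the HFD Klf5+/- libraries and from 31819010 to 44336888 in those labelled Klf5-/-. At these depths 3 counts correspond to 0.0646 to 0.0943 CPM, counts scaled to library size.

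Groups came from the genotype labels and the titles. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined; alternatives chosen after seeing the data are named as such. Each set was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, a quasi-likelihood fit with robust shrinkage and Benjamini-Hochberg adjustment, with an adjusted p of 0.05 as threshold. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM values are TMM-scaled within each set, so levels set side by side across the sets are not on 1 scale. The difference of the genotype effects (HFD minus E17.5) was tested as a contrast in a fit of all 10 libraries. That fit takes 1 spread for each gene across both sets. The sets differ in preparation, sorting and library kit, and what each contributes cannot be told apart. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical in part.

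The 26 gene lists comprised 16 lists of epidermal and metabolic functions and 10 lists of markers of other cell types. Log2 fold changes used edgeR's default prior count. Each list with at least 3 members tested was compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Members past an adjusted p of 0.05 over all genes were counted, as were members past it when adjusted over the list alone. As alternatives camera was run with an estimated correlation, and fry was run, which tests a list against no change and not against other genes. The named genes were Klf5 and, per RNA comparison, the 8 largest rises and the 8 largest falls among genes past the threshold with every library of one genotype on the same side of every library of the other, a mean of at least 2 CPM in the higher group and a symbol other than a Gm number, Rik, pseudogene or mitochondrial name. To these were added up to 4 members of each list that passed, or the 2 with the smallest p where none passed, and 4 genes in each direction for the difference between sets under the same symbol and CPM filters. For the KLF5 peaks, also named were up to 3 passing members of each list with a KLF5 summit near their start. A few of the genes under these rules are not reported here.

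Peak lists were compared by overlap of at least 1 bp, with Wilson 95% intervals that cover counting error only. The count of E17.5 KLF5 peaks overlapping H3K27ac peaks was checked with bedtools 2.31.1. As background, the list whose share is given was shifted 20 times by 100 to 1000 kb. A gene was taken to have a KLF5 peak where a summit lay within 5 kb (5000 bp) of its annotated start, and a peak was taken as promoter-proximal within 1 kb (1000 bp). Called genes were compared with genes tested and not called by Fisher's exact test, two-sided (scipy 1.17.1). Alternatives were size factors in place of TMM, library totals, no low-count filter, a minimum mean of 1 CPM, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library in turn, 1 fit of all 10 libraries, stricter peaks (−log10 q of at least 5), at least 50% of a peak covered, summit inside the other peak, and other windows and backgrounds. Comparisons that need a genome sequence or an hg19 gene annotation, which were not used here, were not run: the KLF motif at summits, the promoter share in HaCaT and the comparison of bound genes between mouse and HaCaT.

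The count test was checked on simulated counts with the observed means, library sizes and per-gene dispersions and 200 changed genes. For E17.5, in 14835 genes, it recovered 42.4% of genes changed 1.5-fold, 62.3% of genes changed 2-fold and 93.8% of genes changed 4-fold, with 13 false among 145 calls. For the HFD set, in 15506 genes, it recovered 0, 2.9 and 59.4% of them, with 17 false among 57 calls. With dispersions on the fitted trend, false calls were 7 of 140 for E17.5 (14865 genes) and 2 of 67 for the HFD set (15484 genes), so the excess of false calls lay in genes of high dispersion.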

Results

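The series concerns KLF5, a zinc-finger transcription factor of epithelia, in relation to sphingolipid metabolism and the barrier of the skin. RNA was sequenced from 3 Klf5+/- and 3 Klf5-/- libraries of sorted E17.5 epithelium. A further set, titled HFD, held 2 Klf5+/- and 2 Klf5-/- libraries of unsorted epidermis. The RNA libraries held between 31819010 and 46445546 counts on genes. Peak lists of KLF5, H3K27ac and open chromatin came as 1 list for each sample.

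Klf5 itself (ENSMUSG00000005148, mm10 chromosome 14, 99298691 to 99313405, plus strand) was not lower in the libraries labelled Klf5-/-. At E17.5 its counts were 8376, 6609 and 6624 in the Klf5+/- libraries. They were 6934, 7211 and 6501 in the libraries labelled Klf5-/-. The levels of 180.6 ± 18.0 and 182.6 ± 12.7 CPM (mean ± SD, n = 3 each) did not differ beyond the spread between libraries (log2 fold change 0.02, SE 0.10, edgeR adjusted p = 0.982). In the HFD set its counts were 2523 and 1575 against 2953 and 4956. That is 52.8 ± 14.1 against 110.4 ± 13.1 CPM (n = 2 each; log2 fold change 1.06, SE 0.23, edgeR adjusted p = 0.0534). The deleted part of the gene is not given in the sources used here, so counts over the whole gene do not check the labels. Every direction that follows rests on the genotype labels.

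At E17.5, 8 genes fell and 5 rose in the libraries labelled Klf5-/-, among 15092 tested with edgeR. Mgst2, a microsomal glutathione S-transferase (chromosome 3, 51660360 to 51682675), went from 27.7 ± 3.91 to 9.70 ± 1.88 CPM (n = 3 each). Its log2 fold change was −1.51 (SE 0.16, edgeR adjusted p = 0.0204). Slc5a1, a sodium-glucose cotransporter, fell from 11.9 ± 1.64 to 5.46 ± 0.103 CPM. The cytochrome P450 gene Cyp2s1 fell from 14.9 ± 1.38 to 7.06 ± 0.796 CPM. Fam25c, Ano7, the organic anion transporter Slco3a1 and the P5-type ATPase Atp13a4 fell by 1.07, 1.06, 0.86 and 0.86 on the log2 scale. The edgeR adjusted p of these 6 genes lay between 0.0308 and 0.0469.

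Among the genes that rose was Krt2, a keratin of the upper epidermis (chromosome 15, 101810689 to 101818169), which went from 1.53 ± 0.126 to 8.47 ± 1.73 CPM (log2 fold change 2.47, SE 0.22, edgeR adjusted p = 0.00779). Serpina3b, a serine protease inhibitor (chromosome 12, 104127996 to 104139545), rose from 3.08 ± 0.446 to 8.82 ± 1.18 CPM (1.52, SE 0.19, edgeR adjusted p = 0.0308). Nat8l, which makes N-acetylaspartate, rose from 43.4 ± 1.73 to 76.2 ± 8.30 CPM (0.81, SE 0.10). Bst1, an ADP-ribosyl cyclase gene, had 3, 4 and 7 counts in the Klf5+/- libraries and 89, 168 and 35 in those labelled Klf5-/- (edgeR adjusted p = 0.0469). The other 2 called genes were the hair keratin Krt36, with 1 count against 164 in all, and 4631405J19Rik, with a log2 fold change of −0.72. They lie outside the rule for named genes and were picked out after their values were seen.

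The count of 13 genes rested on single libraries. It was 513 without the third library labelled Klf5-/-, 3 without the second and 0 without the first, where 1003 genes had an unadjusted p under 0.05. Without each Klf5+/- library it was 5, 3 and 3. It was 461 with DESeq2, 237 without a low-count filter, 8 with limma-voom, 3 in a fit of all 10 libraries and 2 with a minimum mean of 1 CPM. On library totals it was 6, of which 4 were higher and 2 lower. In all, 1512 genes had an unadjusted p under 0.05 in edgeR, where independent genes would give 755 by chance. Other splits of the 6 libraries into 3 and 3 gave 100 to 3043 such genes, so the excess alone does not point to genotype. The genotypes' CPM did not overlap for 14.8% of genes, where chance gives 10%. Another split of the 6 libraries, the first Klf5+/- and the first and second labelled Klf5-/- against the rest, gave 161 genes. The first principal component placed the third library labelled Klf5-/- at −0.9, between the others of its label at 24.8 and 42.9 and the Klf5+/- libraries at −16.3, −33.7 and −16.8. The second component placed the libraries numbered 3 of both genotypes at −23.4 and −36.4, and the other 4 between 6.6 and 27.6.

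Barrier lipid genes stood lower as lists in the E17.5 libraries labelled Klf5-/-. Whether these libraries held the same mix of basal and upper-layer cells was not tested. The largest shift was in acylceramide and very long chain fatty acid synthesis, which builds the long ceramides of the cornified layer. Of its 22 genes 18 had a fold change below 0, with a median log2 fold change of −0.34 (camera adjusted p = 1.45e-14; adjusted p = 0.165 with an estimated correlation). None of them passed over all genes, while 13 were lower and 1 was higher when adjusted over the list alone. Cyp4f39, the omega-hydroxylase of acylceramide synthesis, had 46.1 ± 1.18 against 24.5 ± 5.57 CPM (log2 fold change −0.91, SE 0.14, edgeR adjusted p = 0.0557). Sdr9c7, a dehydrogenase acting on the same lipids, had 29.1 ± 2.11 against 18.2 ± 1.00 CPM (−0.68, SE 0.10, edgeR adjusted p = 0.0557).

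The sphingolipid and ceramide list moved less. Of its 40 members 24 lay below 0 (median −0.05, camera adjusted p = 0.0105; adjusted p = 0.272 with an estimated correlation). None passed over all genes and 5 were lower when adjusted over the list alone. The ceramidase gene Asah2 had 38.1 ± 3.47 against 22.6 ± 4.76 CPM (edgeR adjusted p = 0.0868). Cholesterol biosynthesis had 21 of 24 members below 0 (median −0.13, camera adjusted p = 0.00206; adjusted p = 0.278 with an estimated correlation). None of these passed over all genes or adjusted over the list alone, with Dhcr7 at −0.32 and Mvd at −0.45. Fatty acid and triglyceride synthesis had 15 of 22 members below 0 (median −0.12, camera adjusted p = 0.0130; adjusted p = 0.446 with an estimated correlation). Of these 0 passed over all genes in edgeR and 2 were lower when adjusted over the list alone. Dgat2, the last enzyme of triglyceride synthesis, had 149 ± 21.5 against 81.4 ± 17.9 CPM, and Acsl1 a log2 fold change of −0.61.

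Markers of other cell types moved in these same libraries. All 13 fibroblast markers tested were above 0 in the libraries labelled Klf5-/-, with a median of 1.33 (camera adjusted p = 2.2e-21). This was the single list that also passed with an estimated correlation (adjusted p = 0.0193). Of its members 9 were higher when adjusted over the list alone and none over all genes. The collagen gene Col6a1 had 2.85 ± 0.611 against 8.60 ± 2.35 CPM, and Dpt had 2 counts in the Klf5+/- libraries together against 89. Endothelial markers were above 0 in 7 of 7 (median 0.88, camera adjusted p = 0.00358; adjusted p = 0.21 with an estimated correlation). Their levels were near the floor: Tek had 8 counts against 40 in all, and Pecam1 0.571 ± 0.250 against 1.03 ± 0.065 CPM. Erythroid markers were above 0 in 8 of 8 (median 1.49, camera adjusted p = 0.00974; adjusted p = 0.472 with an estimated correlation). Hba-a1 varied more within groups than between them, at 113 ± 168 against 419 ± 429 CPM, and Hbb-y had 16 counts against 54. Melanocyte markers were above 0 in 9 of 10 (median 0.17, camera adjusted p = 0.0311; adjusted p = 0.278 with an estimated correlation), with Mitf at 0.27 and Tyr at 0.21. No endothelial, erythroid or melanocyte marker passed, over all genes or adjusted over the list alone.

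Among keratinocyte lists, cell cycle genes stood higher. Of 33 members 31 were above 0, with a median of 0.20 (camera adjusted p = 1.68e-06; adjusted p = 0.308 with an estimated correlation). The spindle factor Tpx2 stood at 0.22 and the cell cycle inhibitor Cdkn1a at −0.59. Basal keratinocyte and hemidesmosome genes were above 0 in 19 of 24 (median 0.10, camera adjusted p = 0.0336; adjusted p = 0.496 with an estimated correlation), with Igfbp2 at 0.48 and Ccnd2 at 0.24. Epidermal transcription regulators were below 0 in 24 of 38 (median −0.06, camera adjusted p = 0.0259; adjusted p = 0.383 with an estimated correlation), with Rora at −0.67 and Maf at −0.41. None of the members of these 3 lists passed over all genes or adjusted over the list alone. Interferon response genes were above 0 in 13 of 19 (median 0.08, camera adjusted p = 0.00611; adjusted p = 0.278 with an estimated correlation). None passed over all genes and 2 were higher when adjusted over the list alone, with Ddx58 at 0.51 and Irf7 at 1.49.

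The suprabasal and cornified envelope list went both ways at E17.5. Of 47 members 27 lay below 0 (median −0.11) and the mean was 0.44, while the test called the list lower (camera adjusted p = 0.0336; adjusted p = 0.308 with an estimated correlation). Krt2 was the 1 member past the test over all genes. Adjusted over the list alone 17 members were lower and 6 higher. The suprabasal keratin Krt1 held 3.69, 3.79 and 3.06% of counts in the Klf5+/- libraries and 1.84, 1.61 and 2.55% in those labelled Klf5-/-. The basal keratin Krt5 held 1.41, 1.38 and 1.17% against 1.75, 1.66 and 1.31%. A different mix of cell layers in the sorted cells was not tested and stays open. With replicates 1 and 2 of each group alone, a setting chosen after seeing the data, the direction turned (adjusted p = 0.912).

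The 12 other lists tested at E17.5 did not pass camera, and none of their members passed over all genes. Among keratinocyte lists the medians were −0.07 for PPAR targets (mean 0.29, camera adjusted p = 0.957), 0.07 for hair follicle (adjusted p = 0.122) and 0.09 for sebaceous gland (adjusted p = 0.181). They were −0.12 for tight junction and desmosome (mean 0.05, adjusted p = 0.181), 0.29 for stress and inflammation (adjusted p = 0.122), −0.08 for immediate early genes (adjusted p = 0.195) and −0.01 for KLF and SP factors (adjusted p = 0.107). Immune, Merkel cell and Schwann cell markers had medians of 0.15, 0.12 and 0.22 (camera adjusted p = 0.143, 0.107 and 0.171). Skeletal muscle markers had a median of −0.12 and a mean of 0.05 (adjusted p = 0.821), and smooth muscle and pericyte markers a median of −0.001 and a mean of 0.27 (adjusted p = 0.651). The test took the side of the median for PPAR targets, tight junction and skeletal muscle, and the side of the mean for smooth muscle. Too few adipocyte markers were expressed for a test of all 6 libraries, with Lpl at 0.49 and Lipe at 0.41.

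Some members of these 12 lists passed when adjusted over the list alone: 2 higher for PPAR targets, 1 higher each for hair follicle and sebaceous gland, 1 higher and 3 lower for tight junction, 4 higher and 3 lower for stress, and 2 lower for KLF and SP factors. Krt6a, a keratin of stressed epidermis, had 5.93 ± 1.79 against 24.8 ± 8.09 CPM (log2 fold change 2.06, edgeR adjusted p = 0.0557), and Il1f5 stood at −0.76. Klf12 and Klf3 stood at −1.48 and −0.47. At low levels Cd36 stood at 2.76 and Pparg at 2.12. The log2 fold changes of Dkk4, Trps1, Krt79, Cgn, Dsc2, Krt8 and Krt18 were 0.81, 0.36, −0.69, −0.68, 0.71, 0.74 and 1.17. Those of Hspa8, Hspa1b, Cd3g, Cd74, Foxd3, Cadm4 and Notch3 were −0.28, −0.20, 0.95, 0.58, 0.73, 0.41 and −0.14, and those of Tnni2, Myh3 and Acta2 were −0.28, 0.54 and 1.27.

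The calls of the acylceramide, sphingolipid, cholesterol, cell cycle, fibroblast and endothelial lists passed whichever E17.5 library was left out. Those of fatty acid synthesis (adjusted p = 0.0597 and 0.0834), transcription regulators (0.0899 and 0.0834) and suprabasal genes (0.108 and 0.0834) ended without the first or the second Klf5+/- library, and the suprabasal call also without the third Klf5+/- library (0.0735). Without the third library labelled Klf5-/- the suprabasal (0.634), regulator (0.0919), interferon (0.115), melanocyte (0.128) and erythroid (0.238) calls ended, and 8 lists passed in place of 13. The suprabasal call ended without the second (0.0792). The basal call ended without the second or the third Klf5+/- library (0.0834 and 0.292) and without the first or second labelled Klf5-/- (0.0963 and 0.308). The melanocyte call ended without the second Klf5+/- library (0.119) and the erythroid call without the first (0.138).

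Other lists passed at E17.5 only where 1 library was left out. Without the third Klf5+/- library these were stress (adjusted p = 0.0031), tight junction (0.0348), immediate early (0.00485), KLF and SP factors (0.016), immune (0.00148) and Merkel cell (0.0262). Hair follicle passed without the first Klf5+/- library (0.000231) and stress without the second (0.0433). Immediate early genes (0.0149) and immune markers (0.0124) passed without the first library labelled Klf5-/-. Adipocyte markers, with too few members tested in all 6 libraries, were tested in 5 of these fits and stood higher in each. They passed without the Klf5+/- library numbered 1 (0.0277), 2 (0.0153) or 3 (0.00487) and without that labelled Klf5-/- numbered 1 (2.2e-08), and did not pass without that numbered 3 (0.145). The fat cell gene Plin1 had 0 counts in the Klf5+/- libraries and 0, 102 and 18 in those labelled Klf5-/-.

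**Figure D1:**
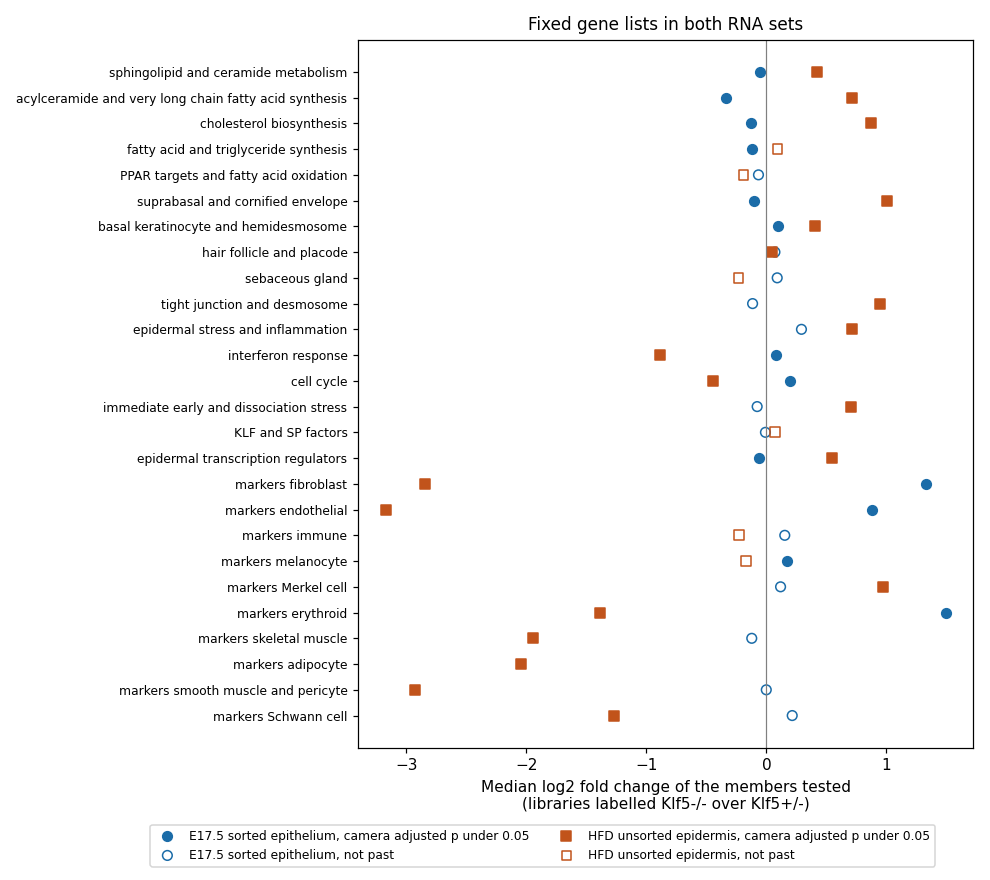
Median log2 fold change (libraries labelled Klf5-/- over Klf5+/-; horizontal axis) of the tested members of each gene list (vertical axis), circles for sorted E17.5 epithelium and squares for unsorted HFD epidermis, filled where the camera adjusted p was under 0.05; adipocyte markers had too few members tested at E17.5. Fibroblast markers lie at 1.33 at E17.5 and −2.85 in the HFD set, and suprabasal genes at −0.11 and 1.00.

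In the unsorted HFD epidermis, 235 genes rose and 637 fell in the libraries labelled Klf5-/-, among 15848 tested with edgeR. As lists, cornified envelope genes stood higher and markers of dermal cell types lower, with few of their members past the test. None of the 26 lists passed with an estimated correlation (lowest adjusted p = 0.387). The largest rises were in small proline-rich and late cornified envelope genes, which encode cross-linked proteins of the horny layer, and in Klk6, a kallikrein protease, and Defb3, a beta-defensin. Sprr1b (chromosome 3, 92436809 to 92438779) went from 107 ± 6.54 to 1079 ± 692 CPM (mean ± SD, n = 2 each; log2 fold change 3.34, SE 0.51, edgeR adjusted p = 0.039). Sprr2i went from 0.494 ± 0.00588 to 8.15 ± 6.06 CPM, Lce3d from 5.29 ± 0.515 to 37.0 ± 22.96 CPM and Klk6 from 8.67 ± 0.340 to 58.4 ± 34.4 CPM. Sprr2g and Lce3f rose with log2 fold changes of 2.66 (SE 0.44) and 2.61 (SE 0.49). Defb3 had 0 and 1 counts in the Klf5+/- libraries and 18 and 143 in those labelled Klf5-/- (edgeR adjusted p = 0.048). Sprr2f had 1 and 3 against 29 and 125 (edgeR adjusted p = 0.0415). In each of these 8 genes the second library labelled Klf5-/- was higher than the first. On simulated counts with the per-gene dispersions of this set, 17 of 57 calls were false, and these lay in genes of high dispersion. Calls of genes with a wide spread between libraries are thus less certain than their adjusted p.

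The largest falls were in Cps1, the first enzyme of the urea cycle, and in genes of blood proteins and other cell types. Cps1 (chromosome 1, 67123026 to 67231259) fell from 7.26 ± 0.307 to 0.134 ± 0.0528 CPM (log2 fold change −5.77, SE 0.49, edgeR adjusted p = 0.032). The complement gene C4b stood at −5.47, the fibrinogen gene Fga at −4.95, the pentraxin gene Ptx3 at −4.92 and the thromboxane receptor gene Tbxa2r at −4.86. Lyg2 (−4.78), the macrophage lectin gene Clec10a (−4.45) and the receptor tyrosine kinase gene Ret (−4.42) followed. The SE of these 7 genes lay between 0.52 and 0.91 and their edgeR adjusted p between 0.0337 and 0.045. Lyg2 held 188 counts in the Klf5+/- libraries and 6 in those labelled Klf5-/-.

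The HFD count of 872 genes also rested on single libraries. It was 36 without the first and 19 without the second Klf5+/- library, and 5389 and 2681 without the first and the second library labelled Klf5-/-, where the lone library of a group is assumed to vary like the others. Of the genes named for this set, Cps1, Krt71 and Krt25 kept their call in all 4 settings. The count was 2906 with DESeq2, 2025 with limma-voom, 2396 without a low-count filter and 3672 in a fit of all 10 libraries. On library totals it was 1340, of which 138 were higher and 1202 lower, against a median over all genes shifted to −0.23. The genotypes' CPM did not overlap for 60.1% of genes, where chance gives 33.3%. The first principal component placed the libraries labelled Klf5-/- at 31.4 and 104.7 and the Klf5+/- libraries at −68.0 and −68.1.

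Keratinocyte differentiation genes stood higher as a list in the HFD libraries labelled Klf5-/-. CPM are shares of a library, and the Klf5+/- libraries held more dermal transcripts. The collagen gene Col3a1 held 0.85 and 1.01% of their counts. It was not among the 5 highest genes of the libraries labelled Klf5-/-. A smaller dermal share could by itself raise keratinocyte genes, and cannot be told apart here from a genotype effect. Of 54 suprabasal and cornified envelope genes 52 were above 0, with a median of 1.00 (camera adjusted p = 5.07e-21; adjusted p = 0.387 with an estimated correlation). Over all genes 12 rose, and 42 were higher and 2 lower when adjusted over the list alone. Cdsn, which encodes corneodesmosin, rose from 214 ± 42.9 to 575.5 ± 16.5 CPM, Cnfn from 196 ± 31.6 to 644 ± 179 CPM and Sprr2h from 7.56 ± 0.391 to 44.4 ± 21.3 CPM. Tight junction and desmosome genes were above 0 in 24 of 27 (median 0.95, camera adjusted p = 5.82e-09; adjusted p = 0.387 with an estimated correlation). Over all genes 6 rose, among them Cldn4 (1.35), Dsp (1.33), Tjp3 (1.12) and Dsg2 (1.01), and 15 were higher when adjusted over the list alone. Basal keratinocyte genes were above 0 in 21 of 24 (median 0.40, camera adjusted p = 0.00353; adjusted p = 0.531 with an estimated correlation), with 4 higher and 1 lower when adjusted over the list alone. The 1 member past the test over all genes was Postn, a matrix protein also made by fibroblasts, which fell from 1807 ± 225 to 645 ± 176 CPM.

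Barrier lipid lists stood higher too, with the same limit of an unlike dermal share. Acylceramide genes were above 0 in 20 of 23, with a median of 0.72 (camera adjusted p = 3.13e-08; adjusted p = 0.387 with an estimated correlation). Over all genes 4 rose, and 17 were higher and 1 lower when adjusted over the list alone. These 4 were the lipoxygenase gene Alox12b (109 ± 28.5 to 293 ± 50.03 CPM), Cyp4f39 (10.9 ± 1.89 to 28.0 ± 6.83 CPM), the transacylase gene Pnpla1 (43.4 ± 5.75 to 89.7 ± 4.14 CPM) and Sdr9c7 (124 ± 15.7 to 230.5 ± 8.89 CPM). Of 41 sphingolipid and ceramide genes 29 were above 0, with a median of 0.43 (camera adjusted p = 0.000105; adjusted p = 0.387 with an estimated correlation). Over all genes 4 rose, and 14 were higher and 3 lower when adjusted over the list alone. The sphingosine kinase gene Sphk1 rose from 43.1 ± 3.99 to 106 ± 16.7 CPM (log2 fold change 1.29, SE 0.19, edgeR adjusted p = 0.0342). Sptlc3, for a subunit of the first enzyme of the pathway, rose by 1.80 (SE 0.31), the ceramide synthase gene Cers3 by 1.28 (SE 0.24) and the sphingomyelinase gene Smpd1 by 0.88 (SE 0.17). Cholesterol biosynthesis genes were above 0 in 22 of 24, with a median of 0.87 (camera adjusted p = 5.54e-10; adjusted p = 0.387 with an estimated correlation). Over all genes 5 rose and 19 were higher when adjusted over the list alone. Among them Sqle, Tm7sf2 and Hmgcs1 rose by 1.39, 1.24 and 0.99.

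In the same libraries markers of dermal cell types stood lower as lists. All 15 fibroblast markers were below 0, with a median of −2.85 (camera adjusted p = 6.26e-12; adjusted p = 0.387 with an estimated correlation). Thy1 (148 ± 13.9 against 37.0 ± 5.22 CPM) and Mfap5 (96.5 ± 27.9 against 7.50 ± 4.02 CPM) fell over all genes, and 8 were lower when adjusted over the list alone. The list averaged 8.66 and 8.95 log2 CPM in the Klf5+/- libraries and 6.75 and 4.67 in those labelled Klf5-/-. All 12 endothelial markers were below 0, with a median of −3.17 (camera adjusted p = 5.54e-10; adjusted p = 0.387 with an estimated correlation). Over all genes Tek, Kdr, Eng and Flt1 fell (−3.49, −3.01, −2.63 and −2.30), and 10 were lower when adjusted over the list alone.

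The smooth muscle and pericyte, adipocyte and skeletal muscle markers had medians of −2.93, −2.05 and −1.94 (camera adjusted p = 0.0012, 0.00253 and 0.00708; adjusted p = 0.387, 0.531 and 0.644 with an estimated correlation). Those of erythroid and Schwann cells had medians of −1.38 and −1.27 (camera adjusted p = 9.41e-06 and 0.00234; adjusted p = 0.387 for both with an estimated correlation). Among members that fell over all genes were Lpl (−2.23) and Plin1 (−2.47) of fat cells, Cadm4 (−1.42) of Schwann cells, and Hbb-bt (−1.52), Hbb-bs (−1.38), Hba-a1 (−1.20) and Alas2 (−1.44) of red cells. Adjusted over the list alone, 2 adipocyte, 2 Schwann cell and 6 erythroid members were lower. No member of the muscle lists passed, with Pdgfrb at −2.98, Cnn1 at −3.87, Myod1 at −3.18 and Myog at −2.33.

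Several other lists moved in the HFD set beside these markers. Interferon response genes were below 0 in 24 of 26, with a median of −0.89 (camera adjusted p = 0.000193; adjusted p = 0.44 with an estimated correlation). Bst2 (−1.79) and Rsad2 (−2.13) fell over all genes, and 6 were lower when adjusted over the list alone. Cell cycle genes were below 0 in 32 of 33, with a median of −0.44 (camera adjusted p = 0.00431; adjusted p = 0.644 with an estimated correlation). None passed either way, with Ccna2 at −0.78 and Ccne2 at −1.14, and the call ended without the second library labelled Klf5-/- (adjusted p = 0.157). Epidermal stress genes were above 0 in 25 of 37, with a median of 0.71 (camera adjusted p = 0.000595; adjusted p = 0.387 with an estimated correlation). Over all genes 4 rose, among them Stfa2 (1.49) and Il1f9 (1.27), while Lcn2 (−4.21) and the chemokine gene Ccl2 (−2.79) fell. Adjusted over the list alone 17 were higher and 6 lower. Immediate early genes were above 0 in 21 of 23, with a median of 0.71 (camera adjusted p = 7.72e-06; adjusted p = 0.387 with an estimated correlation). Hspa1b (1.15) and Junb (0.78) rose over all genes, and 9 were higher when adjusted over the list alone. Epidermal transcription regulators were above 0 in 31 of 39, with a median of 0.55 (camera adjusted p = 0.000369; adjusted p = 0.531 with an estimated correlation). Over all genes 3 rose, among them Hopx (1.43) and Grhl3 (1.29), while Cebpd (−2.39) and Hey1 (−2.33) fell. Adjusted over the list alone 7 were higher and 2 lower.

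Hair follicle genes split in the HFD set. Of 31 members 16 lay above 0 (median 0.05) and the mean was −0.57, while the test called the list lower (camera adjusted p = 0.00526; adjusted p = 0.387 with an estimated correlation). Its 5 members past the test over all genes fell, and 10 were lower when adjusted over the list alone. Among them were the inner root sheath keratins Krt71 (256 ± 10.3 to 26.2 ± 3.34 CPM), Krt25 (157 ± 9.62 to 22.2 ± 4.53 CPM) and Krt27 (−1.79) and the regulator Trps1 (−1.46). Merkel cell markers were above 0 in 9 of 11 (median 0.97, camera adjusted p = 0.0441; adjusted p = 0.387 with an estimated correlation). None passed over all genes or adjusted over the list alone, with Chga at 1.00 and Piezo2 at −1.26.

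Some of these calls rested on 1 library. The hair follicle and skeletal muscle calls ended without the first Klf5+/- library (adjusted p = 0.102 and 0.148), the basal call without the second (adjusted p = 0.136) and the skeletal muscle call without the second library labelled Klf5-/- (adjusted p = 0.383). The Merkel cell call ended with size factors in place of TMM (adjusted p = 0.0518) and without any library but the first Klf5+/- one (adjusted p between 0.0529 and 0.154). PPAR targets passed without the first Klf5+/- or the second library labelled Klf5-/- (adjusted p = 0.0139 and 0.0126), and the immune list without the first library labelled Klf5-/- (adjusted p = 0.0196).

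The other 6 lists did not pass camera in the HFD set. Fatty acid and triglyceride synthesis had a median of 0.09 and a mean of −0.09 (camera adjusted p = 0.362), and KLF and SP factors a median of 0.07 and a mean of −0.32, with the test upwards (adjusted p = 0.82). The medians of PPAR targets, sebaceous gland, immune and melanocyte markers were −0.19, −0.23, −0.23 and −0.17 (camera adjusted p = 0.101, 0.864, 0.13 and 0.427). Dgat2 (1.08), Acsl5 (0.96), the fatty acid binding protein gene Fabp5 (1.79), Klf3 (0.92) and Sp6 (0.83) rose over all genes. Cd36 (−2.09), Angptl4 (−2.32), Fabp4 (−2.13), Mgst1 (−1.53), Pparg (−1.88), Lyz2 (−1.87) and Fcer1g (−1.23) fell. Over all genes the counts were 2 higher for fatty acid synthesis, 1 higher and 5 lower for PPAR targets, 2 lower for sebaceous gland, 2 higher for KLF and SP factors and 2 lower for the immune list. Adjusted over the list alone they were 3 higher and 3 lower, 1 and 6, 1 and 3, 2 and 4, and 1 and 5 in that order. No melanocyte marker passed either way, with Tyrp1 at −1.88 and Kit at −0.45.

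**Figure D2:**
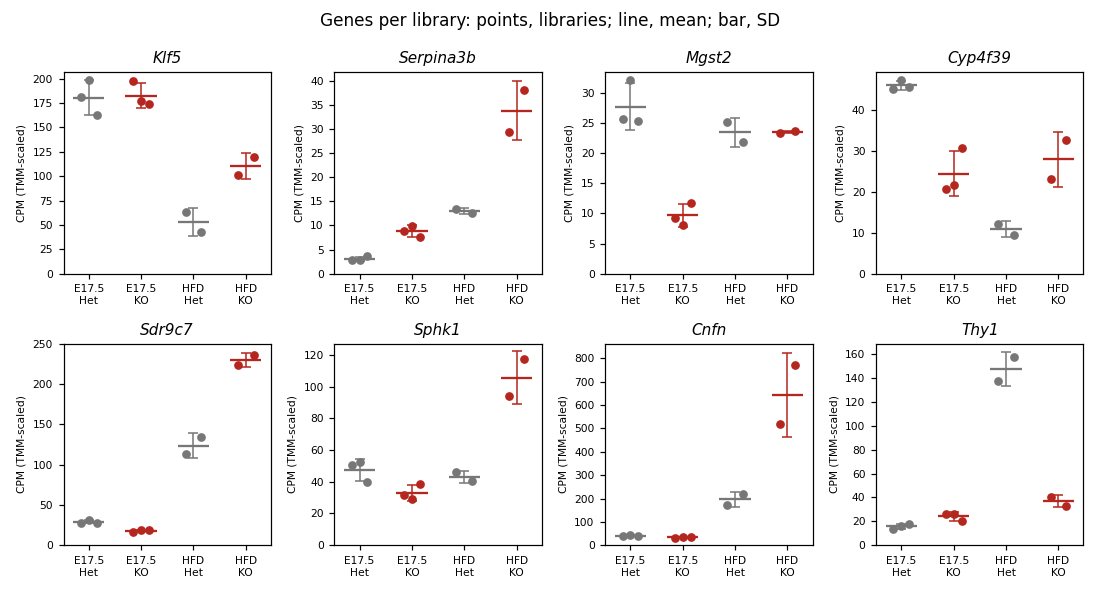
TMM-scaled CPM (vertical axes) of 8 genes in each library of the Klf5+/- (Het) and Klf5-/- (KO) labels of both sets; points are libraries, lines are means and bars are SD, and levels are not on 1 scale across the sets. Cyp4f39 had 46.1 and 24.5 CPM at E17.5 and 10.9 and 28.0 CPM in the HFD set, while Klf5 was not lower in the KO label of either set.

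Genotype effects differed between the sets for many genes, and for several barrier genes they lay on opposite sides of 0. The difference (HFD minus E17.5) was higher for 1221 and lower for 1313 of 17260 genes in edgeR. That fit takes 1 spread for each gene across both sets. Fitted alone, the common dispersion was 0.0298 at E17.5 and 0.0822 in the HFD set. The SE of a difference can thus understate the spread of the HFD libraries, and the count can be too high. For Sdr9c7 the SE was 0.18 in the HFD set alone and 0.16 for the difference. Among the genes with the smallest p, Sdr9c7 had a difference of 1.59 (SE 0.16), Tmem125 of 2.00 (SE 0.22), the transcription factor gene Klf3 of 1.41 (SE 0.16) and the cornified envelope gene Cnfn of 2.02 (SE 0.24). Each was below 0 at E17.5 and above 0 in the HFD set. Lower differences were led by insulin-like growth factor binding proteins and a fibroblast marker: Igfbp5 (−3.10, SE 0.26), Igfbp3 (−2.75, SE 0.25), Thy1 (−2.60, SE 0.23) and Igfbp4 (−2.32, SE 0.19). Sex, preparation, sorting and library kit differed with the set. On library totals the split was 569 higher and 2469 lower, against a median over all genes of −0.31. The count was 1322 and 1266 without the first and second HFD Klf5+/- library, 4467 and 1629 without the first and second HFD library labelled Klf5-/-, 1365 without the second E17.5 Klf5+/- library, and 1426 and 1587 without the first and second E17.5 library labelled Klf5-/-.

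Few calls were shared between the sets. Serpina3b rose in both, 1 gene where 0.0641 is expected of independent lists (Fisher's exact test, two-sided, p = 0.0626), and no gene fell in both (p = 1). At an adjusted p of 0.1, Serpina3b, Serpina3j, Krt6a and Dsc2 rose in both (4 genes, expected 1.14, exact p = 0.0241). At that threshold Hoxd3 and Ildr2 fell in both (2 genes, expected 6.3, exact p = 0.0915). With DESeq2 calls 21 rose in both (expected 9.72, exact p = 0.000639) and 9 fell in both (expected 29.5, exact p = 8.56e-06). Opposite DESeq2 calls were more, with 134 genes lower at E17.5 and higher in the HFD set and 36 the other way. At the adjusted p of 0.1 these were 19 and 6, and at 0.05 none in edgeR. Across 14106 genes tested in both sets, which are not independent replicates, fold changes had a Pearson correlation of −0.231 and a Spearman correlation of −0.272, and 40% had the same sign.

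KLF5 peaks in E17.5 epithelium lay mostly in open, acetylated chromatin. Of 6472 peaks, 74.0% (Wilson 95% interval 72.91 to 75.05) overlapped an H3K27ac peak, of which there were 18155. Of the same peaks 86.3% (85.48 to 87.16) overlapped an ATAC peak, of which there were 41905. Shifted lists gave means of 1.25% and 2.19%. Both marks held 68.7% of the KLF5 peaks and neither held 8.39%. In HaCaT cells 72.7% (72.1 to 73.27) of 22269 KLF5 peaks overlapped an H3K27ac peak, of which there were 39681, against 2.30% for shifted lists. Overlap was higher for stronger peaks, at 63.5% for the weakest and 86.5% for the strongest of 4 classes of E17.5 KLF5 peaks for H3K27ac, and at 56.7% and 89.5% in HaCaT. No regions prone to false signal were removed. The very strongest peaks included some on contigs outside the main chromosomes (JH584304.1 and GL456389.1) and, in HaCaT, on the mitochondrial genome, and these overlapped H3K27ac peaks. Peaks on such contigs or the mitochondrial genome made up 0.6% of the E17.5 and 0.25% of the HaCaT KLF5 list. Of the E17.5 KLF5 summits on main chromosomes 39.5% (38.36 to 40.75) lay within 1 kb of an annotated gene start, as did 47.4% of the H3K27ac and 29.9% of the ATAC summits.

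**Figure D3:**
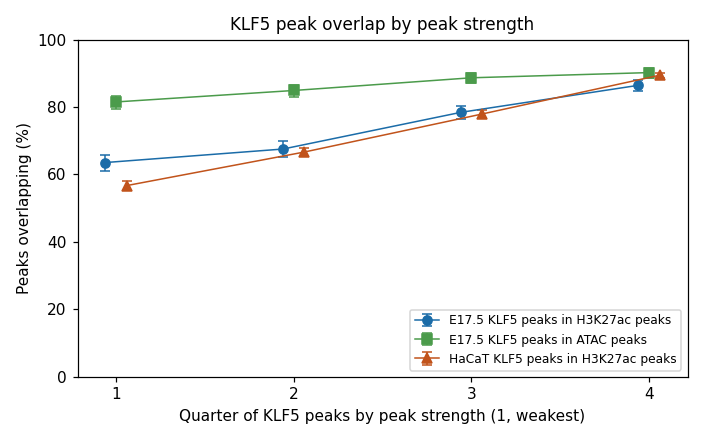
Share of KLF5 peaks (%, vertical axis) overlapping H3K27ac or ATAC peaks in 4 equal classes of peak strength (−log10 q given by the authors, weakest first, horizontal axis), with Wilson 95% intervals as bars. The share goes from 63.5% to 86.5% for H3K27ac at E17.5, from 81.5% to 90.2% for ATAC and from 56.7% to 89.5% for H3K27ac in HaCaT.

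KLF5 summits lay at the starts of several barrier and lipid genes that rose in the HFD libraries labelled Klf5-/-. At Cers3 the peak spanned 66743382 to 66743724 on chromosome 7 of mm10, with its summit 24 bp before the gene start. Fabp5 (chromosome 3, 10012003 to 10012504), Hmgcs1 (chromosome 13, 119690177 to 119690398) and Klf3 (chromosome 5, 64802834 to 64803666) had summits 183, 165 and 141 bp before their starts. For Cldn4 (chromosome 5, 134946960 to 134947299) and Dgat2 (chromosome 7, 99182697 to 99183063) they were 288 and 163 bp before. All these 6 peaks overlapped H3K27ac and ATAC peaks. Fdps, Tjp3, Pkp3, Junb, Hspa1b and Krt1 had summits within 5 kb, that of Krt1 outside H3K27ac peaks and that of Hspa1b outside ATAC peaks. Among lists, 16 of 23 immediate early genes, 10 of 19 KLF and SP factors and 12 of 24 cholesterol genes had a KLF5 peak, against 22.6% of other genes (Fisher's exact test, two-sided, adjusted p = 5.35e-05, 0.0266 and 0.0266). In the same tests 15 of 33 cell cycle genes (adjusted p = 0.0266) and 11 of 24 basal genes (adjusted p = 0.0507) had one. Of sphingolipid genes 13 of 40 had one (adjusted p = 0.349), of acylceramide genes 2 of 22 (adjusted p = 0.441) and of stress genes 0 of 27 (adjusted p = 0.023). These tests of lists were chosen after seeing the data. Of suprabasal genes 10 of 47 (21.3%) had a KLF5 peak. The background was all genes tested at E17.5 and not genes with active promoters. H3K27ac summits lay within 5 kb of the start of 22 of 23 immediate early, 14 of 19 KLF and SP and 22 of 24 cholesterol genes. These tests thus cannot tell the lists apart from active promoters.

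Genes that fell in the HFD libraries labelled Klf5-/- seldom had a KLF5 peak. A summit lay within 5 kb of the start of 53 of 637 such genes (8.3%) and of 21.9% of 14948 genes tested and not called (odds ratio 0.326, Fisher's exact test, two-sided, p = 2.19e-19). Of the genes that rose 58 of 235 had one (24.7%, odds ratio 1.175, exact p = 0.303). That odds ratio was 1.507 within 50 kb (exact p = 0.00198), 1.309 with DESeq2 calls (exact p = 0.000128) and 0.692 by a Mantel-Haenszel estimate stratified by expression (p = 0.0175). At E17.5 none of the 8 genes that fell and none of the 5 that rose had a summit within 5 kb, against 22.65% of other genes (exact p = 0.212 and 0.595). With DESeq2 calls 9 of 125 higher genes had one (odds ratio 0.269, exact p = 3.24e-06), as did 77 of 336 lower genes (22.9% against 23.28%, odds ratio 0.984, exact p = 0.948). As 1 set, the 3386 genes with a KLF5 peak stood higher in the HFD libraries labelled Klf5-/- (median 0.10 against −0.06, camera p = 0.000515; p = 0.0841 with an estimated correlation). At E17.5 the set of 3410 genes did not pass (median −0.003 against 0.02, camera p = 0.215; p = 0.241 with an estimated correlation). These set tests were chosen after seeing the data.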

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

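The tests of the difference for gene lists, and both tests on dermal markers in this part, were chosen only after the result was seen. The results here came up because the genotype effect in the HFD set differed from that at E17.5 by a test of the difference itself. Developmental stage is not given for the HFD set. Sorting, preparation, library kit and sex differed with the set, so none of them can be separated from it.

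Named barrier genes were among those that differed upwards. In all, 24 of 57 suprabasal, 14 of 41 sphingolipid and 17 of 23 acylceramide genes passed the test of the difference, counting either direction. In edgeR 2534 of 17260 genes had a different effect, among them 86 of the 141 genes under the rule for named genes (45 higher and 41 lower in the HFD set). That rule chose genes on these same libraries, some by the difference itself. Their larger share therefore follows at least in part from the rule. Values are differences of log2 fold changes, HFD minus E17.5. For sphingolipid and acylceramide genes they were Sphk1 1.83, Sptlc3 2.10, Cers3 1.66, Smpd1 1.25, Asah2 1.55, Sdr9c7 1.59, Cyp4f39 2.28, Pnpla1 1.65 and Alox12b 2.15. For sterol and fatty acid synthesis they were Dhcr7 1.15, Mvd 1.08, Sqle 1.61, Hmgcs1 1.05, Tm7sf2 1.28, Dgat2 1.97, Acsl1 1.17, Acsl5 1.20 and Fabp5 1.94. Envelope and junction genes had Sprr1b 3.18, Sprr2h 2.35, Cdsn 1.31, Cnfn 2.02, Cgn 1.49, Cldn4 1.18, Tjp3 1.61 and Dsp 1.56. Regulators and stress genes had Klf3 1.41, Rora 1.47, Hopx 1.19, Grhl3 1.66, Hspa1b 1.37, Il1f5 1.56, Il1f9 1.23, Stfa2 1.95 and Cdkn1a 1.16. Klf5 itself had 1.05, and genes lower at E17.5 had Mgst2 1.53, Slc5a1 2.42, Fam25c 1.83, Ano7 1.69, Slco3a1 0.79 and Atp13a4 1.40. Tmem125 had 2.00.

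Named genes of dermal and other cell types were among those that differed downwards. Fibroblast and endothelial genes had Col6a1 −3.99, Dpt −8.28, Thy1 −2.60, Mfap5 −6.63, Postn −1.44, Tek −5.84, Pecam1 −4.002, Eng −3.05, Flt1 −4.12 and Kdr −3.88. Fat, nerve and pigment genes had Lpl −2.70, Pparg −3.96, Cd36 −4.83, Angptl4 −3.06, Foxd3 −2.08, Cadm4 −1.82, Mitf −0.85, Tyrp1 −2.05 and Kit −0.64. The Merkel gene Piezo2 had −1.62, while the Merkel list had a median difference of 0.84. The immune gene Fcer1g had −1.51. The Merkel, immune and melanocyte lists did not pass camera on the difference (adjusted p = 0.305, 0.0874 and 0.0874). Follicle and sebaceous genes had Trps1 −1.80, Krt71 −3.34, Krt25 −3.96 and Mgst1 −1.61. Interferon, stress, cell cycle and regulator genes had Irf7 −1.66, Bst2 −1.86, Lcn2 −6.70, Tpx2 −0.76, Ccna2 −0.99, Ccne2 −1.34, Cebpd −2.50 and Hey1 −2.08. Others were Bst1 −6.34, C4b −6.02, Tbxa2r −8.26, Ret −4.78, Igfbp3 −2.75, Igfbp4 −2.32 and Igfbp5 −3.10. Some of these rest on few E17.5 Klf5+/- counts, so their size depends on the prior count: Tbxa2r had 1 in all, Dpt 2, Mfap5 6, Krt25 6, Flt1 7, Tek 8, Lcn2 10, Bst1 14 and C4b 14.

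By camera on the difference, 14 of 26 lists passed. Higher median differences were suprabasal 1.29, cholesterol 1.07, acylceramide 0.99, tight junction 0.88, immediate early 0.76, epidermal regulators 0.62 and sphingolipid 0.46. Lower ones were endothelial −4.70, fibroblast −4.05, smooth muscle −2.96, adipocyte −2.72, interferon −1.65, Schwann cell −1.57 and cell cycle −0.55. None passed with an estimated correlation, where the lowest adjusted p was 0.103.

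In the HFD set, dermal markers stood lower and barrier genes higher as lists in the libraries labelled Klf5-/-, calls that all ended with an estimated correlation (lowest adjusted p 0.387). Less dermis carried into those libraries may add to this, but the test run, the highest of the 6 dermal list medians at −1.27, restates the pattern and lends it no support. A larger keratinocyte share alone would move basal and suprabasal genes alike if neither list held genes of dermal cells. The basal list holds Postn, which fibroblasts also make and which fell here. A gap between the lists therefore cannot decide on the keratinocyte share. The suprabasal median exceeded the basal one by 0.60 (95% interval over genes 0.36 to 0.89), but between libraries the score difference was −1.43 and −0.76 in Klf5+/- and −0.47 and −0.06 in those labelled Klf5-/-, a gap of 0.29 beside a range of 0.67 within a group, so this share stays open. A genotype effect on differentiation or on the dermis stays open and untested too, as does the way each skin was peeled.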

How the results depend on the processing

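The settings with a term for the replicate numbered 3, with replicates 1 and 2 alone, with the length trend removed and with E17.5-expressed genes or without marker lists were tests chosen after seeing the data. Across alternatives, results for single genes kept their side of the threshold in 1541 cases, while 250 lost the call and 116 gained it. Of the results with a call in either fit, 0 turned direction. Turns of direction with no call in both fits were counted as kept. For lists the counts kept, lost, gained and turned were 374, 93, 15 and 1. The 13 genes at E17.5 and 872 in the HFD set became 6 and 1340 on library totals, 237 and 2396 without a low-count filter, 461 and 2906 with DESeq2, 8 and 2025 with limma-voom and 3 and 3672 in 1 fit of all 10 libraries. With the replicate number as a replicate block they were 42 and 1520. At E17.5, deviations from group means of libraries numbered alike correlated at 0.026, −0.102 and 0.176, against 0.196 for the first Klf5+/- and the second labelled Klf5-/-. A minimum mean of 1 CPM gave 2 and 833, and size factors in place of TMM 13 and 885. Without 1 library at a time they ran from 0 (first labelled Klf5-/-; edgeR, 1003 genes at an unadjusted p under 0.05) to 513 (without the third labelled Klf5-/-) and from 19 (without the second Klf5+/-) to 5389 (without the first labelled Klf5-/-). These fits hold fewer libraries, and in the HFD set the lone library of a group is assumed to vary like the others. At E17.5 a term for the replicate numbered 3 gave 127, replicates 1 and 2 alone 501 and the length trend removed 61. In the HFD set genes of mean CPM of at least 1 at E17.5 gave 374, with fewer genes tested, and leaving out the marker lists 836. The 2534 genes with a different effect became 2406 to 3677 under other settings and 1266 (without the second HFD Klf5+/-) to 4467 (without the first HFD labelled Klf5-/-) without 1 library. Lists past camera, 13 and 20, became 1 and 0 with an estimated correlation (lowest HFD adjusted p 0.387); fry, which asks whether a list changed at all and not against other genes, gave 2 and 0 (lowest HFD adjusted p 0.0888). They were 13 and 21 with the replicate block, 13 and 19 with size factors, and 8 (without the third labelled Klf5-/-) to 18 (without the third Klf5+/-) and 18 to 20 without 1 library. With replicates 1 and 2 alone 11 passed at E17.5 and the suprabasal list turned direction (adjusted p = 0.912). Genes higher in both sets went from 1 to 4 at an adjusted p of 0.1 and 21 with DESeq2, and genes lower in both from 0 to 2 and 9. KLF5 peak shares with stricter peaks, at least 50% covered and summit inside were 71.87, 69.53 and 69.67% for H3K27ac, 85.57, 81.32 and 81.15% for ATAC and 72.08, 66.54 and 66.92% for HaCaT. The promoter share was 50.89% within 5 kb and 41.11% for stricter peaks; the wider window holds the narrower. The odds ratio of a KLF5 peak at higher genes passed with DESeq2 calls at E17.5 (0.269) and in the HFD set within 50 kb (1.507) and with DESeq2 calls (1.309), and turned to 0.692 stratified by expression. For the results that were not kept, the cause was not tested where none is given. Not run for want of a genome sequence or hg19 annotation were the KLF motif, the HaCaT promoter share and the mouse and HaCaT gene comparison. Depth limits genes near 3 counts, which are 0.0646 to 0.0943 CPM.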

Other observations

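Of the tests in this part, those of a wrong label, of a swap, of a mixture, of an effect shared by the libraries numbered 3 and of other splits were chosen only after the result was seen, and the planned fit without the third library labelled Klf5-/- was singled out then. Those on gene length, a setting added after seeing the data, and on KLF5 peaks among expressed genes were written before their own result was seen.

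Without the third library labelled Klf5-/-, 130 genes were higher and 383 lower at E17.5 in edgeR, 513 against 13 with it. Dynap (log2 fold change 6.69), Gprc5a (5.03), Bst1 (4.79), the uroplakin gene Upk1b (4.25), Sprr3 (4.19), Sprr2k (4.05), Bglap3 (4.04) and Coch (3.89) were the highest. Cyp2f2 (−4.07), Skint9 (−2.98), Spib (−2.85), the kallikrein gene Klk13 (−2.47), Mettl7a3 (−2.41), Palm3 (−2.36), Tesc (−2.29) and Serpinb3a (−2.14) were the lowest. Their edgeR adjusted p lay between 1.75e-05 and 0.0313. Mean CPM in Klf5+/- libraries, in the first and second labelled Klf5-/- and in the third was 0.822, 15.6 and 2.35 for Upk1b and 128, 29.3 and 93.2 for Serpinb3a. It was 13.4, 2.41 and 5.58 for Klk13.

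Barrier lipid genes were among those lower in that fit. They included 10 of 22 acylceramide genes (Elovl1, Elovl4, Elovl7, Cyp4f39, Pnpla1, Abhd5, Abca12, Alox12b, Sdr9c7 and Lipm) and 7 of 40 sphingolipid genes (among them Sptlc3, Cers3, Asah2, Acer1, Sphk1 and Sgpp1). Of suprabasal genes 14 were lower, among them Krt1, Krt10, Ivl and Flg, and 7 higher. Of 38 epidermal regulators 7 were lower (among them Grhl1, Grhl3, Ovol1, Cebpa, Maf and Rora), while 6 of 13 fibroblast markers were higher. Because this fit was singled out from the 6 that leave out 1 library after its result was seen, its genes are a hypothesis on the same data.

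At E17.5 the third library labelled Klf5-/- lay between the groups. Its slope from the third Klf5+/- library was taken over 494 genes called in replicates 1 and 2 alone. If it were a Klf5+/- library the slope would be near 0, and if the 2 were swapped below 0. The slope was 0.19 (95% interval over genes 0.13 to 0.25). The third Klf5+/- library stood 0.26 (0.21 to 0.32) from the other 2. The genes were chosen for a difference that involves those 2, so this value lies above 0 in part by that choice. The same choice draws the slope of 0.19 towards 0. The sign of the slope goes against a swap, but it rests on 1 pair of libraries and its interval covers genes only. The counts of Gm10294 and Rpl3-ps1 crossed the label in both libraries numbered 3, as a swap would give, so a swap stays open. As to a wrong label, the shares of the full change were 0.99 for Krt2 and 0.67 for Mgst2, both called with this library included. They were 0.35 for Krt6a and 0.15 for Cd36. The fibroblast score was 3.01 (3.03 and 3.25 in the others of its label, 1.49 to 2.08 in Klf5+/-). The acylceramide score was 5.23 (5.19 and 5.17, against 5.39 to 5.58). Both lists also passed camera with this library included. Among other lists, the suprabasal score of 4.93 (5.6 and 5.4, against 4.69 to 5.1) lay within the Klf5+/- range. The cell cycle score of 6.79 (6.93 and 6.88, against 6.68 to 6.73) lay between the groups. The transcripts Gm10294 and Rpl3-ps1 went with the first and second Klf5+/- libraries, but Rpl3-ps1 did not follow the label in the HFD set. A wrong label stays open. For a mixture with Klf5+/- cells 1 share would hold for all genes; it was 0.16 larger (0.11 to 0.23) in lower than in higher genes, which leaves this open. An effect shared by the libraries numbered 3, which stood apart together on the second principal component (−23.4 and −36.4), may add to the spread, with 127 genes under a term for it, as may length bias, with 61 once each library's length trend was removed, and a true difference between animals was not tested.

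Other splits of the 6 E17.5 libraries into 3 and 3 were fitted the same way. Of the 10 splits 2 gave as many genes as the genotypes, 13 for the genotypes and 161 for the highest other, and 2 gave as many lists, 13 and 14. The splits are too few for a share under 0.05. The split with 161 set the first Klf5+/- library and the first and second labelled Klf5-/- against the rest, which points to a structure of the samples.

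Genes lower in the HFD libraries labelled Klf5-/- seldom had a KLF5 peak. Genes of other cell types, silent in sorted epithelium, might account for this. Among genes with a mean E17.5 CPM of at least 1 the odds ratio was 0.42 (95% interval 0.30 to 0.58), with 44 of 354 against 25.4%. This argues against silent genes as the whole cause. Genes of other cell types can pass this minimum, as fibroblast markers averaged 1.49 to 3.25 log2 CPM in the E17.5 libraries. The filter cannot exclude genes of this kind, and they stay open as a cause. A direct effect of KLF5 was not tested.

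Some transcripts split the libraries. Xist had 17337 to 53513 counts in each E17.5 library and at most 5 in the HFD set, where Ddx3y had 3859 to 5624, so sex goes with the set in the test of the difference. The ribosomal pseudogene Rpl34-ps1 had 97, 1402 and 1226 counts in the E17.5 Klf5+/- libraries and 94, 115 and 1392 in those labelled Klf5-/-, the same split of libraries that gave 161 genes. Rpl3-ps1 had 2696, 2026 and 687 against 454, 524 and 2439, and Gm10294 had 3656, 3307 and 361 against 146, 199 and 3371. In the HFD set Gm10294 followed the label, with 3462 and 2360 counts in the Klf5+/- libraries and 187 and 143 in those labelled Klf5-/-, while at E17.5 both libraries numbered 3 crossed it. Gm6969 (1433 and 1280 against 2 and 7) and Gm4737 (579 and 503 against 6 and 22) also followed the label in the HFD set, and Rpl3-ps1 had 542 and 383 against 3162 and 485.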
